A study of Macaca fascicularis with 16 samples.

How the data were processed

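The series holds bulk RNA sequencing of lung tissue from the cynomolgus monkey (Macaca fascicularis), a macaque. The labels give each of 16 libraries an age class, old or young, and a sex, which makes 4 groups of 4 libraries. Ages in years are not given in the sources used here. The replicate number of each library was taken from its title. Nothing in the labels states that each library came from a separate animal, so the p-values measure the spread between these libraries.

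Per the labels' protocols, the authors extracted total RNA with TRIzol and made libraries with the NEBNext Ultra RNA kit for Illumina. That kit does not mark the strand of a transcript, so reads of a gene and of an overlapping antisense gene cannot be separated. The deposited files hold 1 whole-number count per gene and library, not normalized, under 27966 Ensembl identifiers. The aligner, the counting program, the genome build and the annotation version are not given in the sources used here. Each deposited count file ends with 5 summary entries, whose names are those that htseq-count writes. The entry for reads assigned to no feature held 23.1% to 29.9% of all counts of a library. The feature type that was counted is not given, so these reads need not lie outside annotated genes. The entry for reads that matched more than 1 gene held 1.45% to 1.86%. The entries for low alignment quality, unaligned reads and reads aligned at several places were 0 in every library, so how the authors treated such reads is not recorded. Levels of genes with near-identical copies are therefore uncertain. The summary entries were left out of library sizes and tests.

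The files do not pair the identifiers with gene symbols, and the gene name table used here (40596 genes of assembly T2T-MFA8v1.1) paired 0 of the 27966. For this reason 3 analyses laid down before the data were examined were not run. These were the tests of 55 gene lists with their alternatives, the naming of genes by symbol, and the check of known sex-linked genes by name. Checks of GC content and gene length were void, because no identifier had a value. The rule for named genes had been, per comparison, a fixed number of called genes with a symbol, a mean of at least 1 CPM and the largest log2 fold changes in each direction. It was kept with identifiers in place of symbols and limited to the 2 highest and 2 lowest per comparison. For the age-by-sex interaction, where no gene was called, 2 genes per direction were taken by the smallest p. One gene named there was also called in females. This change to the rule was made after the files were opened.

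Depth ranged from 6529562 to 11718427 counts assigned to genes per library (median 9580040), and 18005 to 18972 genes had at least 1 count. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 15472 genes, and TMM factors ranged from 0.955 to 1.06. One negative binomial model with a mean for each of the 4 groups was fitted to all 16 libraries (glmQLFit, robust). It gave 5 comparisons: old against young over both sexes, in females and in males, the interaction (the age effect in males minus that in females), and males against females over both ages. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts per 1000000 assigned counts, scaled with the TMM factors, and log2 CPM used a prior count of 2. Principal components were computed from log2 CPM. A fold change against a group with no count was computed as a bound, with 3 counts over the whole group in place of 0. Such a bound covers counting error only.

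Age effects in females and males were compared by the correlation across genes of differences of mean log2 CPM. It was set against 100 relabellings of age within each sex, the real labels included. The sexes share no library. The files were checked for repeated libraries: over 24 pairs of libraries of the same group, the chi-square statistic per degree of freedom was 15.6 to 66.6, so no pair matched within sampling noise.

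The procedure was tested on simulated counts made from the real means, dispersions and library sizes, with 200 genes changed and genes drawn independently. For age over both sexes, with 15329 genes tested, it called 63% of genes changed 2-fold and 90% of those changed 4-fold. In the step for females (15305 genes) these shares were 37% and 84%, and in the step for males (15332 genes) 45% and 83%. For the interaction (15325 genes) they were 15% and 63%, and for sex (15316 genes) 66% and 91%. The number of unchanged genes called was 5, 3, 6, 3 and 2 in the same order. These shares hold for 200 changed genes drawn independently and need not hold for the real data.

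Alternatives chosen before the data were examined were RLE factors, no count filter beyond 1 count in all libraries together, a filter of 1 CPM in at least 8 libraries, DESeq2 1.42.0, limma-voom 3.58.1 with library weights, dispersion without robust estimation, the replicate number as a block, and 2 surrogate variables (sva 3.50.0). Models with additive age and sex, with age alone and with the libraries of 1 sex alone, a threshold of 0.10, a minimum log2 fold change of 1, and leaving out each library in turn were also chosen then. After the data were seen, 3 alternatives were added. The first 2 were the share of reads assigned to no feature as a covariate and the omission of old female 1 and old male 3 together. The third was all relabellings in place of 100 for the correlation between sexes.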

Results

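Gene expression was measured by bulk RNA sequencing in lung tissue of cynomolgus monkeys, in 4 libraries each from old females, old males, young females and young males. Between 6529562 and 11718427 counts per library were assigned to genes, and 15472 genes had enough counts to be tested. Genes are given by their Ensembl identifiers, since the files do not pair these with names. Libraries of old animals held 9196700 ± 1629700 counts and those of young animals 9331100 ± 1643200 (SD, n = 8 each), a difference within the spread between libraries (exact permutation test, two-sided, p = 0.868).

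Averaged over genes, age took 12.2% of the sum of squares, sex 6.94% and their interaction 6.73%, where chance alone gives 6.67% to each. The remaining 74.2% lay between libraries within groups, where chance gives 80%. The first principal component held 32.1% of the variance and did not separate the groups. Old female 1 lay at -100.1 and old male 3 at -63.0 on it, against -27.6 to 43.2 for the other 14 libraries. The second component held 9.87%, with young male 1 at its lower end (-52.7).

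**Figure D1:**
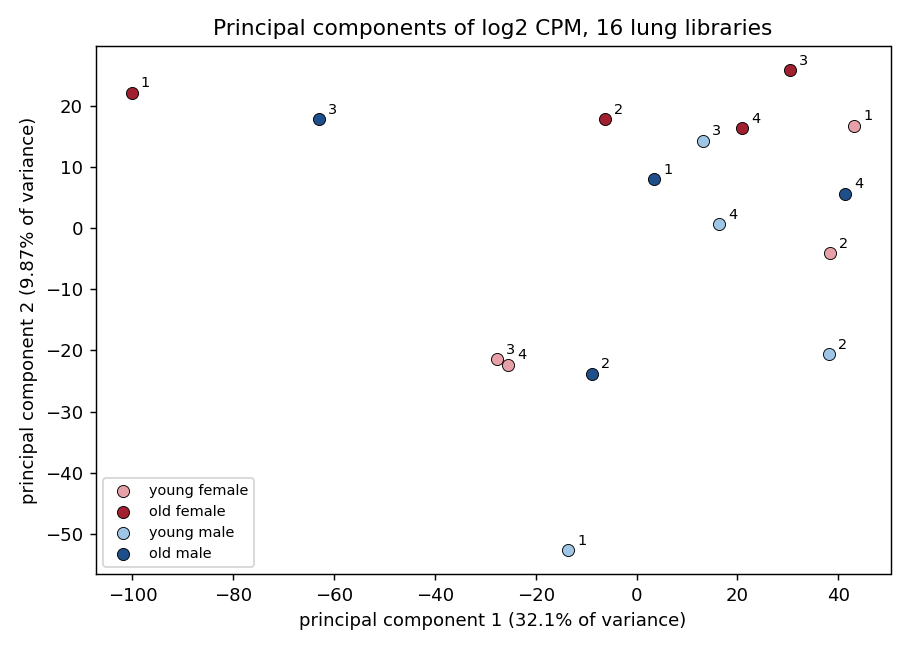
First 2 principal components of log2 CPM for the 16 lung libraries; each point is a library, coloured by group and marked with its replicate number. Old female 1 (-100.1) and old male 3 (-63.0) lie apart from the others on the first component, and young male 1 (-52.7) is lowest on the second.

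The comparison of old with young lungs over both sexes asked which genes differ with age. Among the genes called, ENSMFAG00000000402 had the largest rise, from 132 ± 26.2 counts per 1000000 (CPM) in young to 274 ± 75.1 CPM in old libraries (SD, n = 8 each). This is a log2 fold change of 1.03 (SE 0.15, edgeR adjusted p = 0.0174). ENSMFAG00000002115 rose from 15.6 ± 0.662 to 23.5 ± 2.95 CPM, a log2 fold change of 0.59 (SE 0.089, edgeR adjusted p = 0.0174), and its lowest old library (20.7 CPM) lay above its highest young one (16.3 CPM). The largest fall among the genes called was that of ENSMFAG00000038356, from 23.7 ± 7.91 to 7.58 ± 2.23 CPM, a log2 fold change of -1.68 (SE 0.20, edgeR adjusted p = 0.00724). ENSMFAG00000045597 fell from 151 ± 36.6 to 69.5 ± 32.5 CPM, a log2 fold change of -1.21 (SE 0.18, edgeR adjusted p = 0.0174). In all, edgeR's quasi-likelihood test called 9 genes, 2 higher and 7 lower in old lungs, with folds between 1.43 and 3.20. All 9 had the same direction in females and in males, which their selection on an effect averaged over both sexes favours. In 6 of them the old and young libraries did not overlap, which chance gives for 0.0155% of genes, though called genes are picked for a large separation.

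The number of called genes depended on the tool and on single libraries. DESeq2 called 578 genes (289 higher and 289 lower) and limma-voom 48, both with all of the 9 among them. With RLE in place of TMM factors, 22 genes were called, 11 higher and 11 lower. Without young female 3 the count was 1, without young female 4 it was 2, without old male 4 it was 4, without old male 3 it was 5, without young female 2 it was 15, without old male 2 it was 16 and without old male 1 it was 58. The excess of lower over higher genes also depended on the setting. More genes were higher than lower without old male 1 (42 against 16), with limma-voom (26 against 22) and with surrogate variables (11 against 7). The same held with the share of reads assigned to no feature as a covariate (10 against 9). With old female 1 and old male 3 left out together, 6 genes were called, of which 4 were among the 9. ENSMFAG00000038356 stayed called in each of its 28 alternatives and ENSMFAG00000000402 in 26 of 28. ENSMFAG00000000402 was lost, at edgeR adjusted p = 0.0535 and 0.0542, without young female 3 and without young female 4. ENSMFAG00000002115 stayed called in 25 of 28, and its losses included those without the same libraries, at edgeR adjusted p = 0.0535 and 0.0554. ENSMFAG00000045597 stayed called in 23 of 28. Its edgeR adjusted p was 0.0760 with age alone in the model, 0.0669 without old female 1 and old male 3, 0.0632 without old male 3, 0.0566 without old male 4 and 0.0535 without young female 3.

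**Figure D2:**
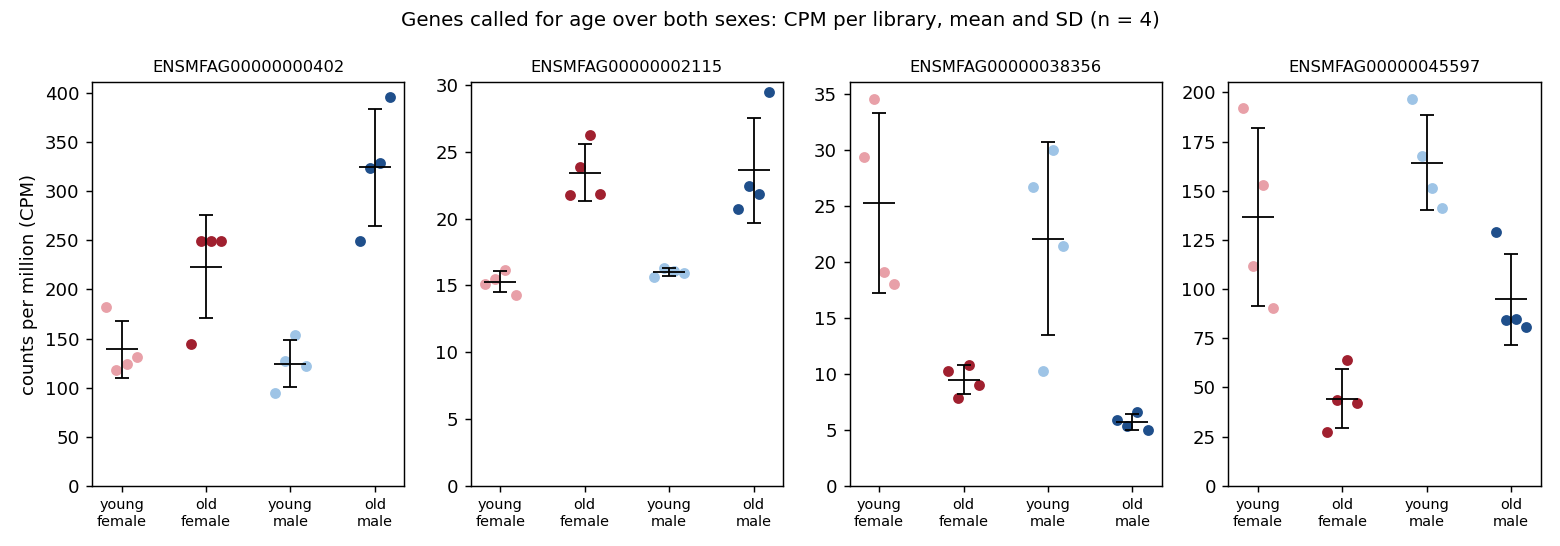
CPM of 4 genes called for age over both sexes, by group; points are libraries, and bars are the group mean and SD (n = 4). ENSMFAG00000000402 and ENSMFAG00000002115 were higher in old libraries (means of 274 and 23.5 CPM), and ENSMFAG00000038356 and ENSMFAG00000045597 were lower (7.58 and 69.5 CPM).

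Below the threshold, more genes differed with age over both sexes than chance gives. At an unadjusted p under 0.05 there were 2738 genes, 1148 higher and 1590 lower in old lungs. On average 774 are expected by chance, but the number can vary widely where genes vary together. Of 100 relabellings of age within each sex, the real one included, 2 reached 2738 (highest other 3237). In females there were 2236 genes, which 1 of 35 splits, the real one, reached. In males there were 1402, which 6 of 35 splits reached (highest other 2134), so chance cannot be excluded there. At a looser edgeR adjusted p under 0.10 there were 227 genes, of which 100 were higher and 127 lower in old lungs. Their median fold was 1.49, and 46 of them differed at least 2-fold. The direction was the same in both sexes for 224 of the 227, which the selection on an effect averaged over both sexes favours.

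In females, ENSMFAG00000046419 rose from 8.03 ± 2.85 CPM in young to 29.1 ± 10.7 CPM in old lungs (SD, n = 4 each), a log2 fold change of 1.86 with an SE of 0.29. ENSMFAG00000032792 rose from 121 ± 24.9 to 267 ± 38.1 CPM, a log2 fold change of 1.14 (SE 0.18). ENSMFAG00000045597 fell from 137 ± 45.2 to 44.2 ± 14.97 CPM, a log2 fold change of -1.63 (SE 0.26). ENSMFAG00000044064 fell from 135 ± 25.3 to 50.2 ± 17.5 CPM, a log2 fold change of -1.42 (SE 0.22). In each of these 4 genes the edgeR adjusted p was 0.0471, and the 4 old female libraries lay on 1 side of all 4 young ones. Their selection as called genes favours such a separation. edgeR called 5 genes in females, 2 higher and 3 lower, of which 1 was also called over both sexes. These 4 genes had log2 fold changes of -0.17, 0.17, -0.79 and 0.09 in males, in the same order, and none was called there.

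The female calls lay close to the threshold. DESeq2 called 400 genes and limma-voom 88, but edgeR called 0 with the 8 female libraries alone, against 2251 at an unadjusted p under 0.05. Leaving out any 1 of 12 libraries also gave 0. The exceptions were young female 2 (5 genes, 3 of them among the 5), old female 1 (2, both among them), old male 2 (11, with all 5) and old male 3 (27, with all 5). With old female 1 and old male 3 both left out, 17 genes were called, 4 of them among the 5.

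In males, ENSMFAG00000000402 rose from 125 ± 24.4 CPM in young to 325 ± 59.7 CPM in old lungs (SD, n = 4 each), a log2 fold change of 1.38 (SE 0.21). ENSMFAG00000038356 fell from 22.1 ± 8.63 to 5.71 ± 0.707 CPM, a log2 fold change of -1.94 (SE 0.29). The edgeR adjusted p of both was 0.0490, and the 4 old male libraries lay on 1 side of the 4 young ones in each gene. Here too the selection of called genes favours such a separation. No other gene was called in males, and both were also called over both sexes. In females the same genes had log2 fold changes of 0.69 and -1.41 (edgeR adjusted p = 0.163 and 0.0849). DESeq2 called 63 genes in males and limma-voom 2, of which 1 was among the 2 of edgeR. edgeR called 1 gene with the 8 male libraries alone, which was neither of the 2, and 0 with RLE factors, against 1420 at an unadjusted p under 0.05. Leaving out any 1 of 12 libraries gave 0 as well, while the count was 4 without old female 1, 1 without old female 4, 1 without old male 3 and 2 without young male 2. Of these, 2, 0, 0 and 1 were among the 2 genes, in the same order.

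Whether the age effect differs between the sexes was tested by the interaction. edgeR called 0 of 15472 genes, with 986 at an unadjusted p under 0.05, where chance gives 774 on average. Of 100 relabellings of age within each sex, the real one included, 33 reached or passed 986 (the highest of the others had 2272). Such a relabelling can turn an age effect that both sexes share into an interaction, so it cannot show whether 986 exceeds chance. The smallest adjusted p of the interaction was 0.141. DESeq2 called 58 genes and limma-voom 4. Among the smallest p, ENSMFAG00000001633 had 196 ± 25.2 CPM in young and 105 ± 12.8 CPM in old females, but 134 ± 7.39 and 169 ± 37.1 CPM in young and old males (SD, n = 4 each). Its age effect was 1.23 log2 units higher in males (SE 0.21). ENSMFAG00000036714 had 3.45 ± 0.998 CPM in young males and 73.7 ± 21.4 CPM in old males. Its level was 71.0 ± 26.4 CPM in young females, and old females spread from 2.73 to 66.7 CPM (log2 difference 5.75, SE 0.98). ENSMFAG00000030780 had 38.9 ± 6.54 and 62.6 ± 14.1 CPM in young and old females, against 57.2 ± 4.57 and 37.9 ± 2.52 CPM in young and old males (log2 difference -1.28, SE 0.22). ENSMFAG00000044863 had 137 ± 17.8 CPM in young and 56.0 ± 10.6 CPM in old males, against 85.1 ± 22.0 and 106 ± 24.4 CPM in females (log2 difference -1.61, SE 0.29). For each of these 4 genes the edgeR adjusted p of the interaction was 0.141, so the differences did not pass the threshold. DESeq2 called all 4, at adjusted p between 2.47e-05 and 0.000258, and over all alternatives their adjusted p reached up to 0.424. The number of genes called was 3 without old female 1, 3 without old male 3, 1 without old female 4, and 8 without old female 1 and old male 3 together.

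**Figure D3:**
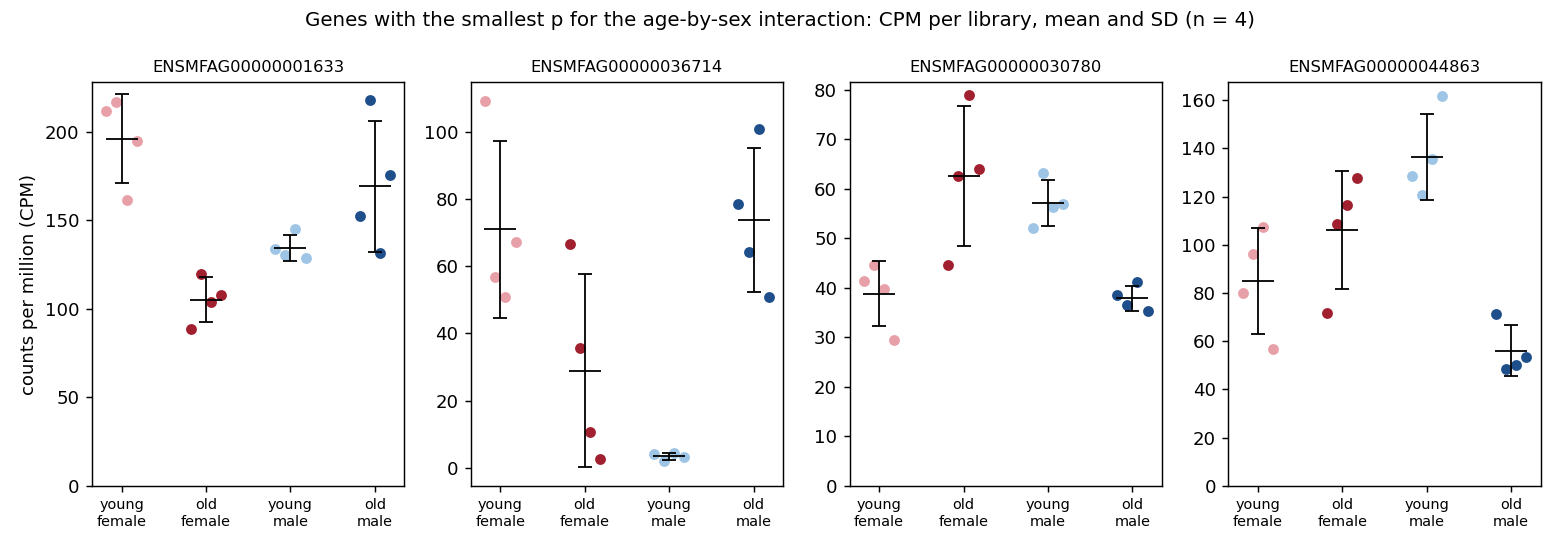
CPM of 4 genes, the 2 in each direction with the smallest p of the age-by-sex interaction, by group. Points are libraries, and bars are the group mean and SD (n = 4). None passed the threshold (edgeR adjusted p = 0.141); ENSMFAG00000036714 lies near 3.45 CPM in young males and ranges from 2.73 to 66.7 CPM in old females.

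Across the 15472 genes, the age effects in females and in males had a Pearson correlation of 0.301, and 62.4% of genes had the same direction in both. Genes are not independent replicates, so the value was set against relabelled ages. Of 100 relabellings within each sex, the real one included, 7 gave a correlation as high, so it was within the range that chance groupings give. Spearman's coefficient was 0.310, which 1 of the 100, the real one, reached (highest other 0.300). Without old female 1 and old male 3 the Pearson correlation was 0.163, and without old female 1 alone it was 0.131.

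Males and females were separated by 3 genes with large differences. ENSMFAG00000041029 had 26.1 ± 3.59 CPM in males and 0.420 ± 0.243 CPM in females (SD, n = 8 each), with 178 to 322 counts in each male library against 1 to 9 in each female one. This is a log2 fold change of 5.87 (SE 0.25, edgeR adjusted p = 2.12e-09). ENSMFAG00000030417 had 0 counts in all 8 male libraries and 114 to 216 in each female one, 18.3 ± 1.95 CPM. This is at least 445-fold higher in females, against a floor of 3 counts over the male group (edgeR adjusted p = 3.64e-08). ENSMFAG00000022423 also had 0 counts in all 8 male libraries, against 12 to 43 in females, at least 61.4-fold higher by the same floor (edgeR adjusted p = 0.00154). Every library followed its labelled sex in these 3 genes. edgeR called 5 genes, 1 higher and 4 lower in males, and the other 2 were lower in males by 1.31-fold and 1.57-fold (edgeR adjusted p = 0.0315 and 0.0382). DESeq2 called 34 genes. ENSMFAG00000041029 and ENSMFAG00000030417 stayed called in each of their 27 alternatives and ENSMFAG00000022423 in 26. The count fell to 3 without any 1 of old female 1, 2 or 4, old male 2 or 4, young female 1, 2 or 4, or young male 3.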

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

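The tests of old female 1 and old male 3 and the omission of both were chosen after the data had been seen. So were the test that leaves out the farthest library of each group and the thinning of libraries to 1 depth. The covariate for reads assigned to no feature and the adjustment over 7 genes alone were also chosen then. The relabelling tests and Dixon's test were set before.

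Old female 1 had a lower mean Spearman correlation with the other libraries (0.906) than the rest of its group, by a gap that Dixon's test calls outlying. The same test picked out young female 1 for that measure (0.956) and young male 1 for its share of reads assigned to no feature (29.9%). It also picked out old female 1 for ENSMFAG00000000402 (144.5 CPM, lower than the other old females) and old male 1 for ENSMFAG00000045597 (129 CPM, higher than the other old males). These are 5 of 88 groups of values tested, and chance alone picks out about 1 in 20.

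For 6 of the 7 genes called for age within a sex, the age effect differed between the sexes when the interaction was adjusted over those 7 genes alone. The age effect in males minus that in females, in log2 units, was 1.23 for ENSMFAG00000001633, -0.97 for ENSMFAG00000032792, 1.52 for ENSMFAG00000044064, 0.83 for ENSMFAG00000045597, -2.02 for ENSMFAG00000046419 and 0.70 for ENSMFAG00000000402. The adjusted p over the 7 genes in edgeR ranged from 0.000143 to 0.0411. Picking genes for a large effect in 1 sex favours such a difference, and over all genes tested none of them passed (smallest adjusted p 0.141).

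Old female 1 and old male 3 stood apart on the first principal component. Low depth is argued against, since old male 3 held 10670475 counts, above the median of 9580044.5 for the other 14 libraries, and old female 1, with 6817068 counts, still lay at -98.5 on the first component (the other 14 from -26.1 to 40.9) when all libraries were thinned to 6529562 counts. The 726 genes at least 2 log2 units higher in old female 1 than in the other old females varied together in the 12 libraries that are not old female. Their mean pairwise correlation was 0.602, against at most 0.0189 in 1000 random gene sets of similar expression. Without old male 3 as well, the value over 11 libraries was 0.555 (at most 0.0223 in random sets). The set thus rose and fell together from library to library. This does not decide whether old female 1 alone had a defect. The random sets were not matched on how much genes vary, and a defect could also raise genes that vary together elsewhere. What these genes are was not tested, because their identifiers have no names here. A defect in old female 1, a difference in the piece of lung sampled, a state of the animal and age itself stay open.

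Old animals of the same sex differed more from one another than young ones. The mean distance within groups (1 minus Spearman's coefficient) was 0.0213 higher in old animals, which did not pass an exact one-sided relabelling test (p = 0.147, 4900 relabellings). Without old female 1 and old male 3 the difference was -0.00219, or -10.3% of its value with all libraries, but the prediction written for this was wrong, because both had been picked for lying far out and both are old, so the difference had to fall. With the library farthest from its group left out of each of the 4 groups, and the same done in every relabelling, the difference was 0.00241 (exact one-sided relabelling p = 0.294, 4900 relabellings). A greater variation of old animals, 2 unusual libraries and chance all stay open.

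More genes than chance gives reached an unadjusted p under 0.05 for age over both sexes, 2738 against 774. The share of reads assigned to no feature was 25.2% ± 1.21 in old and 26.3% ± 1.86 in young libraries (SD, n = 8 each). This difference did not pass (exact permutation test, two-sided, p = 0.199). It is argued against as the whole cause, since 2230 genes were found with that share as a covariate, 1864 of them among the 2738. Of 100 relabellings of age within each sex, the real one included, 2 gave as many genes, with 3237 in the highest of the others, which is under the limit of 5 set beforehand and argues against chance. Without old female 1 and old male 3 there were 2023 such genes, and without young male 2 alone 2116. The relabellings were not repeated without these libraries. Age stays as the explanation the design names, along with anything else that differed between the old and young animals, none of which was tested.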

How the results depend on the processing

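The omission of old female 1 and old male 3 together and the covariate for reads assigned to no feature were chosen after seeing the data. So was the use of all relabellings, and the other alternatives were chosen before. No named gene changed direction in any alternative. The numbers of called genes moved, and the cause was not tested unless stated. For age over both sexes, 9 genes were called. The count was 22 with RLE factors, 22 without the count filter, 22 with the stricter filter, 578 with DESeq2, 48 with limma-voom, 18 with surrogate variables, 19 with additive age and sex, 21 with age alone and 19 with the covariate. Each of these 9 settings kept at least 7 of the 9 genes. A threshold of 0.10 gave 227 genes and a minimum log2 fold change of 1 left 4, as both must by construction. Leaving out 1 library gave 1 to 58.

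In females, where 5 genes were called, the count was 3 with RLE factors, 3 without the filter and 3 with the stricter one. It was 400 with DESeq2, 88 with limma-voom, 37 with surrogate variables and 17 without old female 1 and old male 3. It was 0 without robust dispersion, 0 with female libraries alone and 0 with the covariate. A threshold of 0.10 gave 107, and leaving out 1 library 0 to 27. In males, where 2 were called, it was 0 with RLE factors, 63 with DESeq2, 0 without robust dispersion, 6 with surrogate variables, 1 with male libraries alone (neither of the 2), 0 with the covariate and 7 at 0.10, and 0 to 4 without 1 library. The interaction, with 0 called, gave 58 with DESeq2, 4 with limma-voom, 4 with surrogate variables, 8 without old female 1 and old male 3, and 0 to 3 without 1 library. For sex, with 5 called, it was 3 without the filter, 34 with DESeq2, 9 with surrogate variables, 3 at a minimum log2 fold change of 1 and 3 to 7 without 1 library.

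The correlation of age effects between the sexes was 0.301. Spearman's coefficient of 0.310 passed its relabelling test (1 of 100, highest other 0.300) where Pearson's (7 of 100) did not. This was a narrow margin, and Spearman's coefficient was not set against all relabellings. Among all 2450 relabellings, 267 gave a Pearson correlation as high. Leaving out 1 library gave 0.131 to 0.340.

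The replicate numbers showed no clear pairing of the libraries, though a weak pairing could go unseen in correlations over all genes. Of the 24 pairs of libraries with the same number in different groups, 5 had deviations from the group means that correlated above 0.1 (range -0.459 to 0.413), and 2 of the 16 libraries correlated best with their own number. With the number as a block, 6 genes were called for age over both sexes, 5 of them among the 9, so 4 were lost, ENSMFAG00000002115 among them (edgeR adjusted p = 0.0606). For sex, 2 of the 5 were kept and 3 lost, with ENSMFAG00000022423 among them (edgeR adjusted p = 0.0913). None was called in females, in males or for the interaction (0 each).

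The tests of 55 gene lists and all their alternatives were not run, because no identifier was paired with a symbol. The simulated test used the real depths of 6529562 to 11718427 counts per library, 4 libraries per group and the real dispersions. It called 63% of 2-fold changes for age over both sexes and 15% for the interaction. Which of these settings sets the shares was not tested. The simulation changed 200 genes and drew genes independently, while the real fits called 9 and 0 genes in these 2 comparisons. The simulated shares are therefore not the power in the real data, where genes vary together between libraries.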

Other observations

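The tests of the gene set, its comparison with the relabelling that called the most genes, and the relation of the second principal component were chosen after the data had been seen. The relabelling tests themselves were chosen before.

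A set of 726 genes, picked in old female 1, had a median range of 4.84 log2 units between the highest and lowest library. The mean log2 CPM of the set was 4.86 in old female 1, 3.57 in old male 3, 2.85 in young female 3, 2.75 in young female 4 and 2.44 in young male 1, against 0.630 in old male 4 and 0.660 in young female 1. In old male 3, a library of the other sex, 680 of the 726 genes lay above the mean of the other old males, by a median of 2.05 log2 units. The mean of the set was 2.12 in old and 1.66 in young libraries, a difference that did not pass (exact permutation test, two-sided, p = 0.465, n = 8 each), and 0 of its genes were called for age over both sexes.

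The second principal component followed the share of reads assigned to no feature over the 16 libraries. Pearson's r was -0.823 (permutation p = 0.00016, adjusted p = 0.0016) and Spearman's rho -0.721 (permutation p = 0.00216, adjusted p = 0.0216), adjusted over 10 relations between 5 library measures and the first 2 components. Without the 2 libraries farthest from the median share, r was -0.615. Old libraries lay at -23.8 to 25.8 on this component, the old females among them at 16.3 to 25.8, and young libraries at -52.7 to 16.7. Whether the component also differs with age was not tested, so it need not reflect the share alone. None of the other 9 relations passed after adjustment.

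Relabelling the libraries asked how often other groupings call as many genes as the real one. For age over both sexes, 3 of 100 relabellings of age within each sex called at least 9 genes, the real one included, which argues against chance, but the highest of the others called 357. That relabelling had put 7 of the 8 libraries with the highest mean of the gene set above on 1 side, at a mean of 2.68 against 1.11 log2 CPM. None of the 100 separated the set further. That relabelling was picked for its number of calls, and the second most was 49. Whether the genes it called belong to the set, and whether such a structure is larger than the difference between ages, was not tested. In females, 1 of 35 splits, the real one, called 5 genes or more, and the highest of the others called 1, which argues against chance in this setting only. A share of 1 in 35 is the smallest these splits can give and was not adjusted for the 5 comparisons. edgeR called 0 genes with the female libraries alone. In males, 2 of 35 splits called 2 genes or more (highest other 2), so chance cannot be excluded. For the interaction, with 0 genes called, this test is void, since each of the 100 relabellings must reach that count (highest other 1). For sex, 1 of 100 relabellings of sex within each age, the real one, called 5 genes or more (highest other 1). For the correlation of age effects between the sexes, 7 of 100 were as high (highest other 0.444), so chance cannot be excluded.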
